A study of Homo sapiens with 4 samples.

How the data were processed

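The series holds 4 libraries of Ishikawa cells, 1 H3K9me3 ChIP and 1 input library for each of NC and OE-KDM4A. Chromatin was fixed with formaldehyde and sheared by sonication, per the labels' protocols. Trimmomatic, Bowtie 1.1.2, MACS2 2.1.0 and the hg38 build are named in the submitters' processing notes, without the settings used or the role of each. The peak lists of the 2 ChIP libraries were analysed. The input libraries were not analysed here by themselves, and total read counts and any other replicate were not used here, so the depth of each library is unknown.

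Each list gives 1 line per summit, in the narrowPeak layout, and each list belongs to 1 library. The deposited score column equals 10 times the −log10 q, without its decimals, in all lines. The fold enrichment in the deposited lists is a linear ratio of ChIP to background at the summit, as the authors' peak caller writes it. The deposited lists also give −log10 p and −log10 q values per peak, made by the authors. The lowest −log10 q was 1.31 in both lists. Lines with the same start and end were counted as 1 peak, which removed 69 of 1234 lines in NC and 402 of 4187 in OE-KDM4A. No line lay off chromosomes 1 to 22, X and Y.

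Gene positions came from a RefSeq gene table of GRCh38.p14, the assembly that hg38 names. The table gives gene spans without strand, exons or sequence, and this changed the plan in several ways. Distances to a transcription start became distances to either end of a gene span, and the 5 kb upstream of a gene became 5 kb at both ends. The split into exons and introns, the repeat share and the GC content were left out, with the alternative of 200 bp around the summit. In place of assembly gaps, random placement avoided the longest stretch of each chromosome without a gene. Chromosome length was taken as the position of the last gene. Of 18 ERR metabolic target genes 17 were matched.

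Lists were compared by overlap of at least 1 bp, set beside 1000 random placements within each chromosome. Shares have exact (Clopper-Pearson) 95% intervals. The ratio of peak numbers has the exact interval of 2 counts. The interval of a difference of medians came from 10000 resamplings of regions. No test between conditions was run, since each has 1 library. A gene was counted where a peak overlapped its span or the 5 kb beside it, and the count of a gene list was set among 10000 random lists matched on biotype and on 20 bins of gene length. That percentile describes these libraries only. The gene lists, the comparisons and the first set of alternatives were fixed before the data were examined.

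The same holds for the rule for named regions and genes. It takes the 10 peaks of each list with the highest −log10 q, the 10 highest among those found in that list only, ESRRG and KDM4A, every gene with a peak from the lists of up to 60 symbols, the 10 protein-coding genes with the most peaks (ties in alphabetical order), and up to 10 genes with the highest −log10 q from each larger family. Peaks on chromosome Y are not described, and some items of the gene lists are not reported here. Genes of windows that are named beside a density come from the same rule, while the windows were chosen after their values were seen.

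The gene-free stretches with 5 Mb on either side, the windows of 10 Mb, the shares of chromosomes 12 and X and the values at the summit described next were chosen after seeing the data. MACS2 is known to compute fold enrichment as (pileup + 1) / (background + 1) and p from a Poisson distribution around the background. From these formulas the ChIP pileup, a whole number of stacked fragments, and the control background at each summit were recovered from the deposited fold and −log10 p. A whole-number pileup gave the deposited −log10 p within 0.001 for 98.8% of NC and 99.6% of OE-KDM4A peaks. For regions called in both lists, each NC peak was set beside the overlapping OE-KDM4A peak with the highest −log10 q. Each value was taken at the summit of its own list, so summits can differ. An OE-KDM4A peak can serve several NC peaks, and this choice can favour OE-KDM4A. A background within 0.1% of the lowest of its list was counted as the lowest. These values are used for the control background in the report and in the closing observations.

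The alternatives were higher limits on q and fold enrichment, joined peaks, other overlap rules, other distances to a gene, other gene sets and other matching of random lists. The steps were tested on simulated data. With 200 planted overlaps among 1165 placed peaks, 200 were found, and 7 of 200 random gene lists fell outside the central 95%. All 500 simulated pileups were recovered within 1%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.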

Results

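H3K9me3, a histone mark of silenced heterochromatin, was mapped by ChIP-seq in Ishikawa cells, an established human endometrial cancer line. Cells labelled NC, with no treatment, were set beside cells labelled OE-KDM4A. KDM4A is a demethylase that acts on methylated lysine 9 of histone H3, and the series title links it to ERRγ, the orphan nuclear receptor encoded by ESRRG, and to the cell cycle. Each condition had 1 immunoprecipitated library and 1 input library, and the comparison rests on the 1 peak list deposited for each immunoprecipitated library. With 1 library per condition, no difference between the conditions has a replicate check. Intervals of shares and of ratios of peak numbers are exact 95% intervals that cover counting error only, and the number of reads behind each list is not given in the sources used here.

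The first question was whether the lists differed in how much of the genome carried called H3K9me3 peaks. The NC list held 1165 peaks and the OE-KDM4A list 3785, a ratio of 3.25 (3.04 to 3.47). The NC peaks covered 188222 bp and the OE-KDM4A peaks 671371 bp, a ratio of 3.57 (7.62 among peaks with a fold enrichment of at least 5). Peaks were short in both, with a median width of 142 bp in NC and 135 bp in OE-KDM4A and mean widths of 162 and 177 bp. The medians lie near the shortest peak of each list, 121 bp in NC and 108 bp in OE-KDM4A. Widths and covered bases therefore describe the called peaks and do not measure how far H3K9me3 extends. The widest peak measured 794 bp in NC and 3083 bp in OE-KDM4A. The ratio of peak numbers was 2.42 among peaks with a −log10 q of at least 10 (328 against 794) and 5.61 among peaks with a fold enrichment of at least 5. A fold limit is not equivalent between the lists, since fold enrichment was higher in OE-KDM4A at 318 of the 404 regions called in both. Each region is an NC peak beside the overlapping OE-KDM4A peak of highest −log10 q, which can recur and can favour OE-KDM4A. The control background recovered at the summit was lower in OE-KDM4A at 285 of the 324 regions called in both lists within the longest gene-free stretches of the chromosomes, and at 44 of the 80 such regions elsewhere. Without chromosome Y, the background of the regions elsewhere was lower in OE-KDM4A at 25 of 59 and higher at 34. Over all peaks, 1861 in OE-KDM4A (49.2%) and 96 in NC (8.24%) stood at the lowest background of their list. These shares also depend on the depth of each input, which is unknown.

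The peaks with the highest −log10 q in both lists lay mostly near centromeres, and those of NC also included subtelomeric regions. Strength here means rank by −log10 q, not fold enrichment. The fold enrichment of the 10 NC peaks ran from 2.67 to 7.29, against a list median of 4.39. For the peak ranked 1 it was 3.04 in NC over a control background of 1744, and 23.25 in OE-KDM4A over 347.8. The peak with the highest −log10 q was at the same place in both lists, chromosome 3 from 93470368 to 93470788 in NC and from 93470361 to 93470800 in OE-KDM4A (hg38), 402 kb from PROS1, which encodes the anticoagulant protein S. In NC, 3 of the 10 strongest peaks lay on chromosome 5 between 49601507 and 49661838, at least 734 kb from EMB. The NC peak ranked 3 fell within DUX4, the double homeobox gene of the chromosome 4 subtelomere (190179507 to 190179674). The one ranked 6 lay on chromosome 18 from 108397 to 108540, within LOC112268408 and 4.62 kb from the nearest protein-coding gene, LOC124905450. In OE-KDM4A, 3 of the 10 strongest peaks lay on chromosome 1 (125179900 to 125180625, 143213042 to 143213379 and 143264442 to 143264940) and 3 on chromosome 16 (46387659 to 46388130, 46389603 to 46391445 and 34592510 to 34592935). A pair of others lay on chromosome 4, at 49149156 to 49149853 and 49709230 to 49710175, 87.1 kb and 647 kb from CWH43. Reads from near-identical copies of these repeats can be placed at any copy, so the exact position and the source copy of such peaks are uncertain.

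Peaks were counted in the longest stretch of each chromosome without a RefSeq gene, extended by 5 Mb at both ends. This stretch holds the centromere on most chromosomes, and together the stretches made up 13.3% of the genome. They held 513 of the 1165 NC peaks (44.0%, 41.2 to 46.9) and 1319 of the 3785 OE-KDM4A peaks (34.8%, 33.3 to 36.4). The shares were 73.6% and 63.6% at a −log10 q of at least 5, and the difference was gone at 10, with 79.3% and 78.6%. Among peaks found in both lists the share was 80.2% (76.0 to 84.0) for NC, against 24.8% (21.8 to 28.1) among peaks found in NC only and 29.7% (28.2 to 31.3) among those found in OE-KDM4A only.

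The lists shared mainly these regions. Of the NC peaks, 404 (34.7%, 31.9 to 37.5) overlapped an OE-KDM4A peak, and 386 OE-KDM4A peaks (10.2%, 9.25 to 11.2) overlapped an NC peak. At a −log10 q of at least 5 and 10 the shares were 65.8% and 74.7% for NC and 22.6% and 29.1% for OE-KDM4A, and at a fold enrichment of at least 5 that of OE-KDM4A was 6.31%. Within 5 kb of a peak of the other list it was 20.1%. Outside the gene-free stretches the overlap was 80 of 652 NC peaks (12.3%, 9.85 to 15.0). Random placement of these peaks on their own chromosomes, outside the stretches, gave a mean of 0.191 overlapping peaks and at most 2 in 1000 placements. With both lists at 1165 peaks by q value, 354 (30.4%, 27.8 to 33.1) were shared. Within the NC list, shared peaks had a median −log10 q of 17.1 (quartiles 7.99 and 39.5) and unshared peaks 2.64 (1.86 and 4.30). Within the OE-KDM4A list the medians were 31.9 (10.2 and 163) and 3.58 (2.47 and 5.76). Fold enrichment went the other way in NC, with a median of 3.87 for shared and 4.42 for unshared peaks. The shared NC peaks stood on a median control background of 19.6, against 1.13 for the unshared. In OE-KDM4A the median fold enrichment was 8.92 for shared and 4.98 for unshared peaks. The fold enrichment and q of each peak are the authors' own values.

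Peaks found in one list only also included strong ones. In NC, the strongest of these lay on chromosome 18 from 60018192 to 60018336, with a fold enrichment of 43.6, 114 kb from PMAIP1, a gene of the apoptosis pathway. Others lay on chromosome 21 from 8434090 to 8434251 within RNA45SN1, a ribosomal RNA gene, and at 8420096 to 8420531 within the pseudogene CDC27P10. A further peak lay on chromosome 14 from 46509432 to 46509590, within LOC124903309 and 141 kb from the nearest protein-coding gene, RPL10L. In OE-KDM4A, the strongest lay on chromosome 5 from 49659784 to 49660376. It was followed by chromosome 1 peaks at 125182304 to 125183224 and 125178689 to 125179419, a chromosome 4 peak at 49092743 to 49093067, 30.7 kb from CWH43, a chromosome 10 peak at 42078906 to 42080085, 494 kb from ZNF33B, and a chromosome 13 peak at 18211722 to 18212550 within FAM230C. Several of these lay within a few kb of a peak present in both lists.

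Peaks in genes differed in place between the lists. Outside the gene-free stretches, 21.3% of the NC peaks (139 of 652, 18.2 to 24.7) had their summit within 1 kb of a gene end, against 7.32% under random placement. In OE-KDM4A the share was 6.04% (149 of 2466, 5.13 to 7.06), against 6.34% under random placement. For ends of protein-coding genes the shares were 12.6% (10.1 to 15.4) in NC and 2.96% (2.33 to 3.71) in OE-KDM4A. The few peaks shared outside the stretches lay near gene ends in 33.8% of cases for NC (27 of 80) and 33.3% for OE-KDM4A (26 of 78). Chromosome Y is included in these counts, and 59 of the 80 NC peaks remain without it. Of all 404 shared NC peaks, 16 lay within 5 kb of a DUX4 or DUX4-like gene, whose copies share reads. With the gene-free stretches included, the shares were 13.0% (11.1 to 15.0) in NC and 4.23% (3.61 to 4.92) in OE-KDM4A. They were 9.15% and 2.64% at a −log10 q of at least 10 and 23.1% and 10.1% within 3 kb.

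**Figure D1:**
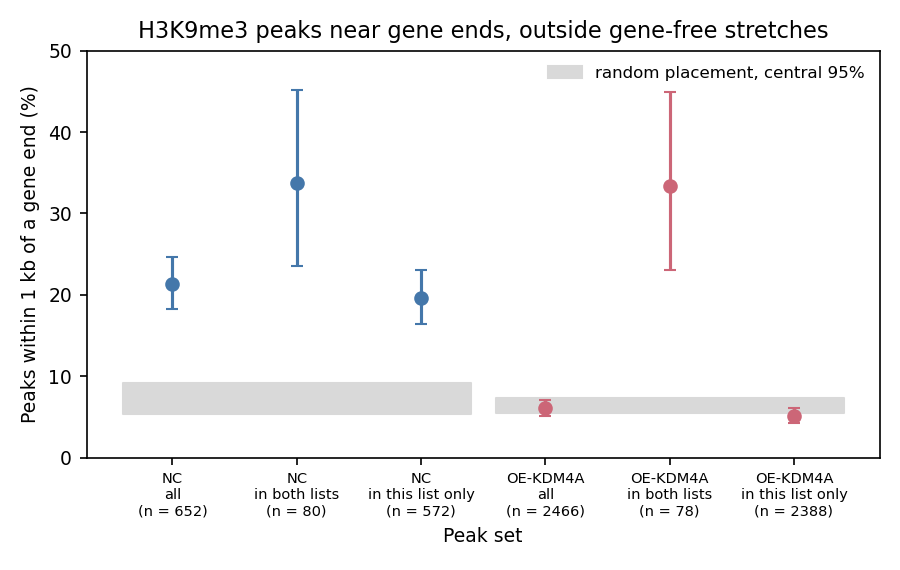
Percent of peaks with the summit within 1 kb of a gene end (y axis) for all peaks of each list, those in both lists and those in that list only (x axis), outside the gene-free stretches. Points are shares, bars exact 95% intervals and grey bands the central 95% of 1000 random placements of the whole list; NC stands at 21.3% and OE-KDM4A at 6.04%.

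In OE-KDM4A the genes with the most peaks were led by GRIP1 and CTNNA3. These are raw counts, not corrected for gene length or for the peak density of the region. CTNNA3 spans 1851 kb and NAALADL2 1370 kb, and several of the genes lie in the crowded windows described below. The counts therefore do not show that a gene was marked more than its surroundings. GRIP1, which encodes a scaffold protein of glutamate receptors, held 9 peaks over its 722 kb span on chromosome 12 and none in NC. CTNNA3, an alpha catenin gene on chromosome 10, and NAALADL2 on chromosome 3 held 6 each, again with none in NC. ITPR2, a calcium release channel gene, SYT1, a synaptic vesicle calcium sensor gene, and VPS13B held 5 each, and LMNTD1, MSRB3, LPP and NLGN1 held 4 each. Of these 10 genes, LPP and NLGN1 had 1 NC peak each. In NC no gene held more than 3 peaks. LOC124905450 on chromosome 18 held 3 peaks in each list, DUX4 and SLC25A21 held 2 in each list, and FRG2C held 2 in NC and 1 in OE-KDM4A. The cadherin gene CDH4, METTL26, MTA3, SLCO3A1, SYN3 and TGFBR3 held 2 NC peaks each and no OE-KDM4A peak. DUX4, FRG2C and ZNF717, which also held 4 OE-KDM4A peaks, have near-identical copies elsewhere, so their reads are uncertain. Of 20037 protein-coding genes, 491 had a peak within their span or 5 kb of it in NC, 1070 in OE-KDM4A, and 95 in both. OE-KDM4A also had more such genes at the same limits, with 233 against 86 in NC at a −log10 q of at least 5, 56 against 28 at 10 and 497 against 146 at a fold enrichment of at least 5. These limits are not equivalent between lists with different controls. At regions called in both lists, fold enrichment was higher in OE-KDM4A at 318 of 404 (median log2 change 0.95), with a median ChIP pileup change of 0. Counting only genes with a gene end within 5 kb of a peak, the lists were closer, at 279 in OE-KDM4A and 249 in NC. With both lists at equal length it had fewer (159 against 491), but its list then held peaks with a −log10 q of at least 5.91, while that of NC was whole, weak peaks included.

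Across chromosomes the NC peaks outside the gene-free stretches were densest on the gene-rich chromosomes 22 (0.911 per Mb) and 19 (0.865 per Mb) and sparsest on X (0.0708 per Mb), chromosome Y not being considered. The OE-KDM4A peaks were densest on chromosome 12, at 2.43 per Mb. Chromosome 12 held 11.8% of them (291 of 2466, 10.6 to 13.1), against 6.13% of the NC peaks (40 of 652, 4.42 to 8.26). Chromosome X held 6.16% (5.25 to 7.19) in OE-KDM4A and 1.53% (0.738 to 2.80) in NC. Chromosome 19, which carries many zinc finger gene clusters, held 3.86% of all NC peaks (45, 2.83 to 5.14) and 1.11% of all OE-KDM4A peaks (42, 0.801 to 1.5). Among peaks with a −log10 q of at least 10, chromosome 19 held 2 in NC (0.610%) and 3 in OE-KDM4A (0.378%).

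**Figure D2:**
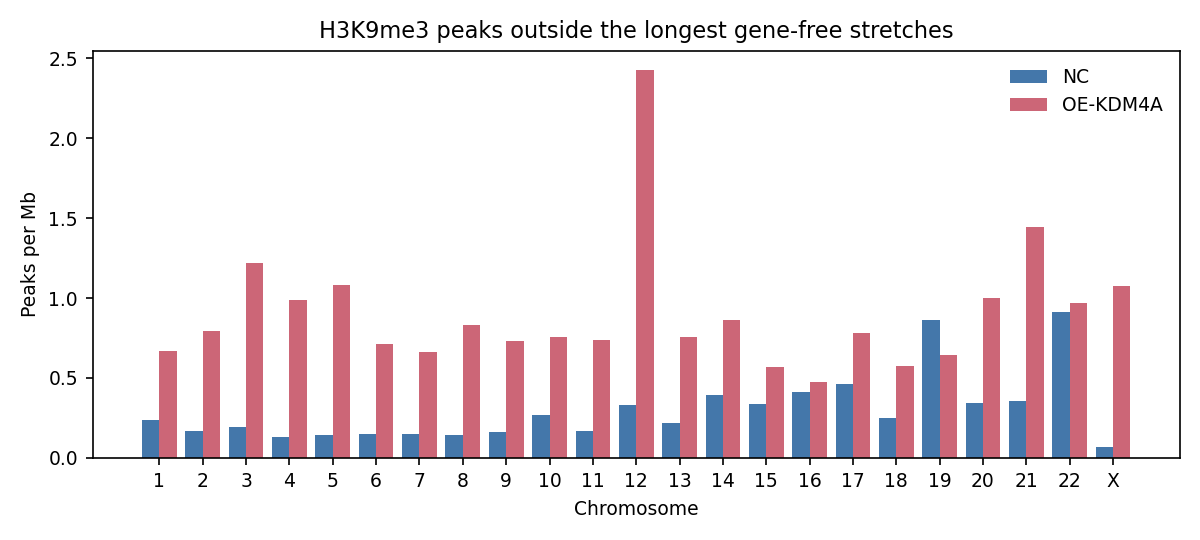
Peaks per Mb outside the longest gene-free stretches (y axis) on chromosomes 1 to 22 and X (x axis), blue bars for the 1 NC list and red bars for the 1 OE-KDM4A list. OE-KDM4A reached 2.43 per Mb on chromosome 12, and NC was above OE-KDM4A on chromosome 19 (0.865 against 0.643 per Mb).

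Peaks found in OE-KDM4A only were crowded in some windows of 10 Mb, with 33 windows on 13 chromosomes at 2 or more times the median density. Chromosome 12 had 7 of these windows. On chromosome 12 their density was 5.50 per Mb from 60 to 70 Mb, the window that holds MSRB3 and GRIP1, and 5.30 per Mb from 70 to 80 Mb, which holds SYT1. It was 0.60 per Mb from 80 to 90 Mb. On chromosome 3 it was 4.20 per Mb from 170 to 180 Mb, which holds NLGN1 and NAALADL2, and on chromosome 5 it was 2.90 per Mb from 90 to 100 Mb. On chromosome 21 it was 3.90 per Mb from 10 to 20 Mb, with 1.30 protein-coding genes per Mb. The longest gene-free stretch of chromosome 21 ended at 5010453, so this window may hold repeats near the centromere. The median of all 264 windows of 10 Mb was 0.70 per Mb. Peaks found in NC only reached 0.60 per Mb at 60 to 70 Mb of chromosome 12 and 0.30 per Mb at 170 to 180 Mb of chromosome 3.

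**Figure D3:**
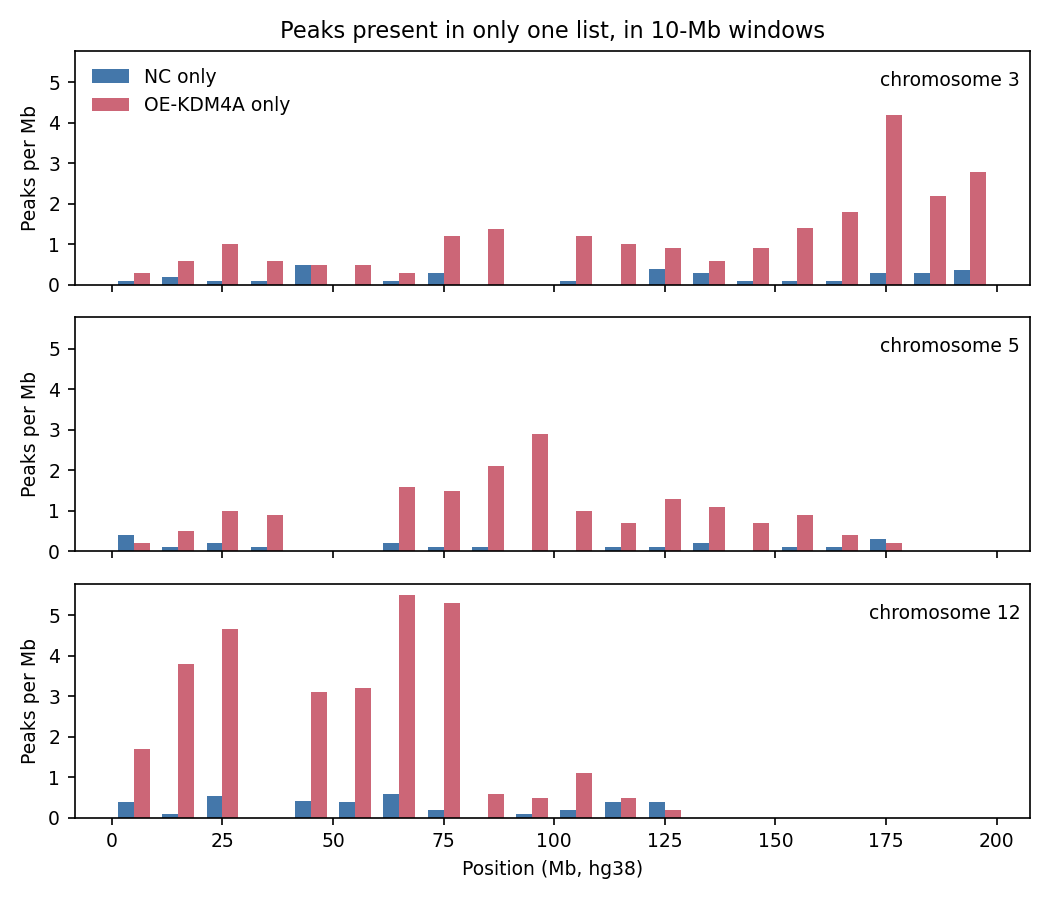
Peaks per Mb (y axis) along chromosomes 3, 5 and 12 (x axis, position in Mb, hg38) in windows of 10 Mb, blue bars for peaks found in NC only and red bars for peaks found in OE-KDM4A only; windows that lie mostly in the gene-free stretch are left blank. OE-KDM4A stands at 5.50 per Mb from 60 to 70 Mb of chromosome 12 and at 0.60 per Mb from 80 to 90 Mb.

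Neither ESRRG nor KDM4A carried a called peak in either list. No peak lay within ESRRG (chromosome 1, 216503246 to 217137702) or within 100 kb of it. The nearest NC peak was 3.69 Mb away, and the nearest OE-KDM4A peak was 304 kb away, at 217441215 to 217441331 (fold enrichment 6.30). No peak lay within KDM4A (chromosome 1, 43650149 to 43705518) or within 100 kb of it, and the nearest peaks were 7.28 Mb away in NC and 387 kb away in OE-KDM4A. A list of called peaks shows neither that the mark was absent from a gene nor that it differed there.

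Among the ERR and steroid receptor genes, none had a peak in NC. In OE-KDM4A, ESR2, the estrogen receptor beta gene (chromosome 14, 64311387 to 64311509), and the coactivator gene NCOA1 (chromosome 2, 24597942 to 24598059) had 1 peak each. Of 57 cell cycle genes, none had a peak in NC and 3 had 1 in OE-KDM4A, namely the cyclin gene CCNA2 (chromosome 4, 121823674 to 121823790, at the end of its span), E2F5 and the checkpoint kinase gene CHEK2, the last 2 outside the gene span. The cell cycle count stood at percentile 81.2 in OE-KDM4A and 16.7 in NC among 10000 random gene lists of like gene length. The −log10 q of these 5 peaks lay between 1.43 and 2.66, below the list's median of 3.58. None of 17 ERR metabolic target genes had a peak in either list.

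Among 25 genes of the H3K9 methylation machinery, KDM4C, a demethylase gene related to KDM4A, had 2 peaks in OE-KDM4A (chromosome 9, 6757875 to 6758000 and 6867212 to 6867365), and no gene had one in NC. Of 26 imprinted genes, GRB10 and PLAGL1 had a peak in OE-KDM4A and none did in NC. The ribosomal protein gene RPL13A was the 1 housekeeping gene of 20 with a peak, in NC only. None of 39 HOX genes had a peak in either list. PAGE2B was the 1 cancer-testis gene of 77 with a peak, in NC, and KRT25 the 1 keratin gene of 149, in OE-KDM4A. For these 6 lists the counts stood between percentile 11.2 (keratin genes in NC) and 84.6 (housekeeping genes in NC). The peaks named here were weak, with a −log10 q between 1.85 (KRT25) and 3.66 (GRB10). The list medians were 3.83 in NC and 3.58 in OE-KDM4A. The KDM4C peaks had recovered pileups of 9 and 10 fragments.

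Zinc finger genes, a family whose clusters are known to carry H3K9me3, stood on opposite sides of the random lists in NC and OE-KDM4A. Of 570 genes, 4 had a peak in NC (ZNF414, ZNF567, ZNF578 and ZNF813), and 12 was the median of random lists, which put the count at percentile 0.44. In OE-KDM4A 32 had a peak, and the random median was 20 (percentile 99.7). No zinc finger gene had a peak in both lists. The strongest in OE-KDM4A were ZNF717 with 4 peaks (highest −log10 q 16.1), ZNF521 (11.7), ZNF14 (6.71), ZNF136 (6.10) and ZNF875 (5.62). A split by chromosome 19, chosen after seeing the data, used random lists also matched on chromosome, with fewer length bins. Its random medians are thus not parts of those above. On chromosome 19, 15 of 264 zinc finger genes had a peak in OE-KDM4A (random median 8, percentile 99.9) and 4 in NC (random median 10, percentile 0.755). Off chromosome 19, 17 of 306 had one in OE-KDM4A, which did not stand apart (random median 13, percentile 89.2), and 0 in NC (random median 6, percentile 0.03). Over all 570 genes, with the first matching, the NC count was at percentile 7.17 and 26.5 with a −log10 q of at least 5 and 10. It was at 8.11 with a fold enrichment of at least 5 and 4.38 for the gene span alone. The OE-KDM4A count did not stand apart at these q and fold limits (79.3, 81.9 and 86.6), with a gene end within 5 kb (65.2), without the gene-free stretches (22 genes, 79.5) or with both lists at equal length (4 genes in each list, percentile 74.2 in OE-KDM4A). Olfactory receptor genes, also known to be silenced outside the nose, had 9 of 392 with a peak in OE-KDM4A (percentile 92.8), among them OR2C1, and none in NC (0.355). None of 53 clustered protocadherin genes, neighbours on chromosome 5 of which many have overlapping spans, had a peak in either list. Their percentile is left out, since they are far from independent. Zinc finger and olfactory receptor genes also lie in clusters, which the random lists do not copy, so their members are not independent either.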

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

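No paired analysis was possible because each condition has 1 library. The gene-free stretches and every value given without them or for their flank, and the ratios between the lists other than those of peak number and covered bases, were chosen after seeing the data. The OE-KDM4A list stayed the longer one under every alternative tried, while most shares moved beyond their counting interval. The order of the lists turned for protein-coding genes with a peak, from 2.18 times as many in OE-KDM4A to 0.324 times at equal list length, where the OE-KDM4A list ends at a −log10 q of 5.91 and that of NC keeps its weak peaks, and for the percent outside genes, from 56.8 in NC and 59.2 in OE-KDM4A (ratio 1.04) to 78.7 and 76.2 (0.968) at a −log10 q of at least 5. Without the gene-free stretches, 30.8% of the NC peaks lay outside genes, and none of 1000 random placements outside the stretches gave a lower share. In OE-KDM4A the share was 43.1%, against a mean of 39.6% under placement, and all 1000 placements gave a lower share. Values below are in the order −log10 q of at least 5, −log10 q of at least 10 and fold enrichment of at least 5, where all moved. The cause of these moves was not tested.

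The ratio of peak numbers (3.25) was 2.78, 2.42 and 5.61, and 3.78 without the gene-free stretches. The ratio of covered bases (3.57) was 3.82, 4.08 and 7.62, and 3.29 with peaks within 5 kb joined. The shared percent of NC peaks (34.7) was 65.8 and 74.7 at the higher q limits, 25.2 with 50% reciprocal overlap, 39.1 within 5 kb and 12.3 without the stretches. That of OE-KDM4A peaks (10.2) was 22.6, 29.1 and 6.31, then 7.74 with 50% reciprocal overlap, 14.2 within 1 kb, 20.1 within 5 kb and 3.16 without the stretches. At equal length (30.4%) it was 26.1% ranked by fold enrichment and 45.2% for 500 peaks each.

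The percent near a gene end in NC (13.0) was 10.7 and 9.15 at the higher q limits, 23.1 within 3 kb, 7.12 for protein-coding genes and 21.3 without the stretches. In OE-KDM4A (4.23) it was 2.64 at the higher q limit of 10, 3.41 at fold enrichment of 5, 10.1 within 3 kb, 2.03 for protein-coding genes and 6.04 without the stretches. NC was above OE-KDM4A in each of these. The chromosome 19 percent in NC (3.86) was 1.21, 0.610 and 2.53, and 5.98 without the stretches. In OE-KDM4A (1.11) it was 0.652, 0.378 and 0.651. The percent in the stretches in NC (44.0) was 73.6, 79.3 and 52.5, and 32.8 with a flank of 1 Mb. In OE-KDM4A (34.8) it was 63.6, 78.6 and 47.1, and 24.5 with that flank.

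Protein-coding genes with a peak in NC (491) numbered 86, 28 and 146, and 249 with a gene end within 5 kb. In OE-KDM4A (1070) they numbered 233, 56 and 497, 279 with a gene end within 5 kb and 159 at equal list length. Zinc finger genes in NC (4) numbered 0, 0 and 1, and 2 with a gene end within 5 kb. In OE-KDM4A (32) they numbered 6, 2 and 12, 9 with a gene end within 5 kb and 4 at equal length. Their percentile in NC (0.44) was 7.17, 26.5 and 8.11, and 4.38 for the gene span alone. In OE-KDM4A (99.7) it was 79.3, 81.9 and 86.6, then 65.2 with a gene end within 5 kb, 74.2 at equal length and 79.5 without the stretches. Fewer peaks remain under the higher limits and at equal length, which lowers the gene counts by construction. Of the planned values for the results above, 51 moved and 9 lost their call, against 23 within their bounds. Of the other planned values, 101 stayed within their bounds and 56 moved. Total read numbers are unknown, so how far depth limits the weak peaks cannot be given.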

Other observations

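All tests in this part were chosen after the results were seen. At the 404 regions called in both lists, the recovered ChIP pileup had a median log2 change (OE-KDM4A over NC) of 0.00 (quartiles −0.47 and 0.40), with 198 regions higher and 194 lower in OE-KDM4A. Each region is an NC peak beside the overlapping OE-KDM4A peak of highest −log10 q, with values taken at each list's own summit. The control background at these summits had a median log2 change of −1.34 and was lower in OE-KDM4A at 329 regions. It was −1.52 in the gene-free stretches (285 of 324 lower) and −0.30 elsewhere (44 of 80 lower). Without chromosome Y it was −1.53 in the stretches (282 of 320 lower) and turned to 0.33 elsewhere (quartiles −1.22 and 0.93), with 25 of 59 regions lower and 34 higher. The regions differed by place. On chromosome 1, 28 of 29 had a higher pileup in OE-KDM4A (median log2 change 0.77), 25 of them in blocks at 125 Mb and 143 Mb within the gene-free stretch. On chromosome 16, 25 of 29 were higher (0.62), while on chromosome 17, 27 of 40 were lower (−0.44). Several chromosome 16 regions were set beside the same OE-KDM4A peak, such as the one with a pileup of 1935, which repeats its value. At 6 regions within 5 kb of DUX4 or a DUX4-like gene, chromosome Y left out, all 6 were lower in OE-KDM4A (−0.83). Copies of such repeats share reads, so these regions are not independent of each other. They are values of 1 library per condition and are not scaled by the lowest backgrounds, whose log2 difference was 0.16.

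The longer OE-KDM4A list was set against technical differences. The lowest background, which follows the number of ChIP reads times the fragment length, was 1.12 times higher in OE-KDM4A, and after scaling OE-KDM4A down by that factor the ratio of peak numbers was 3.12 (2.92 to 3.33). Taking the shortest peaks (121 bp in NC and 108 bp in OE-KDM4A) as the fragment lengths puts the read number at 1.25 times that of NC and the scaled ratio at 2.60 (2.43 to 2.78), so both values argue against a deeper ChIP library as the whole cause. A lower control background in OE-KDM4A may account for part of the excess, as 49.2% of its peaks stood at its lowest background against 8.24% in NC. That share also depends on the depth of each input, which is unknown. Low recovered backgrounds were spaced more widely in OE-KDM4A (such as 1.556, 2.334 and 3.112) than in NC (1.703, 2.129 and 2.555), so input sampling may differ. The ratio was 2.19 (2.04 to 2.35) with OE-KDM4A backgrounds moved by the median changes at shared regions. It was 2.75 (2.57 to 2.95) with the changes without chromosome Y, which lower the backgrounds outside the stretches. The shared regions there go both ways and the background of NC at the peaks found in OE-KDM4A only is not known, so a lower control background cannot be told apart from an effect of OE-KDM4A, which stays untested with 1 library per condition.

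The higher ChIP pileup on chromosome 1 lay mostly at blocks around 1q12, where a gain of DNA copies in cells with raised KDM4A is a candidate explanation. Extra copies would add reads to the input as well. The background change on chromosome 1 (median log2 −2.79 over 29 regions) lay below that on the other chromosomes (−1.29 over 350 regions, Y left out), a difference of −1.49 (−2.34 to −0.67, from resampling regions that share reads, so too narrow), and was −3.68 and −2.82 in the 2 blocks. The values gave no sign of extra copies. The background also fell on other chromosomes by unlike amounts, such as −0.98 on chromosome 20 and −1.91 on chromosome 16. A gain of the size of the pileup excess (0.77) could be hidden in that spread, so extra copies are not excluded. More H3K9me3 at these blocks, and another division of reads among repeat copies in the OE-KDM4A libraries, also stay open and were not tested.

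OE-KDM4A peaks were crowded in windows on 13 chromosomes, with an abrupt end near 80 Mb of chromosome 12, and extra DNA copies of these segments in the line are a candidate explanation. In the 33 windows with at least 2 times the median density, peaks found in NC only were 1.15 times as dense as elsewhere (0.889 to 1.47). These windows include the one at 10 to 20 Mb of chromosome 21, which may hold repeats near the centromere. The control background was above its lowest value at 44.7% (41.2 to 48.3) of the OE-KDM4A peaks in these windows and at 41.4% (38.9 to 43.9) elsewhere. The pooled value hides windows that differ. The count was 22 of 42 at 170 to 180 Mb of chromosome 3 and 30 of 55 at 60 to 70 Mb of chromosome 12. It was 9 of 29 at 90 to 100 Mb of chromosome 5. Neither value decides: both intervals allow a modest gain, and a control background that rises with copy number could hold back NC peaks. A first bound of 1.5 on the NC density would have argued against extra copies, but it was replaced by 1 after the value was seen for that reason, so extra copies and an effect of OE-KDM4A cannot be told apart.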
